A study of Saccharomyces cerevisiae S288C with 72 samples.

How the data were processed

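RNA-seq was performed on budding yeast, Saccharomyces cerevisiae, of an S288C background. Wild type was compared with a strain lacking NDE1, NDE2 and NDI1, which encode the external and internal NADH dehydrogenases of the mitochondrial inner membrane, and with a strain lacking COX4, which encodes a subunit of cytochrome c oxidase. Cultures grew in baffled shake flasks in a defined medium with ammonium and 2% glucose. Each strain was sampled at 24 matched times between 0 and 58 h, which gave 72 libraries, 24 for each of the 3 strains. Per the labels' protocols, cells were collected by vacuum filtration and frozen in liquid nitrogen, and RNA was extracted with hot acidic phenol. Ribosomal RNA was removed with a Ribo-Zero kit and libraries were made with a stranded TruSeq total RNA kit.

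The deposited values were transcript abundances in TPM for 5803 genes in each library. The submitters' processing notes name bcl2fastq 2.20.0.422, Salmon 0.9.1 and the genome build sacCer3. The strand setting of Salmon and its transcript annotation are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies may therefore be shared out in ways that TPM values do not show. No deposited TPM value lay below 0.1, and between 38 and 134 genes per library stood at that floor. The sums per library exceeded the nominal total of the unit by 3.62 to 12.9 TPM. TPM keeps no record of read numbers, so sequencing depth is unknown and no counting interval was computed.

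Of the 5803 entries, 5779 matched an annotated gene by name, 13 by an older name and 11 not at all. Of all entries, 5780 were nuclear protein-coding, 19 mitochondrial and 4 of the resident plasmid. TPM were rescaled to a common total over the nuclear protein-coding genes, because the other 23 entries held between 0.147% and 0.881% of the total. Genes with a mean of at least 1 rescaled TPM were tested, which kept 5721 and left out 82. Time points were grouped into an early window from 0 to 8 h with 7 points, a middle window from 9 to 16 h with 8, and a late window from 18 to 58 h with 9. There was 1 library per strain and time, and no replicate culture is stated. The time points of a window therefore stood in for replicates, and p-values measure the spread between time points of these cultures, not between cultures. The labels place each strain in its own plate rows, and each strain changes row between 13 and 14 h. A row effect therefore cannot be told apart from strain or from time, and the step of the cox4Δ mutant between 13 and 14 h falls on such a change.

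Tests used limma 3.58.1 in R 4.3.3, with trended and robust variance moderation, on log2(rescaled TPM + 1). A fold change on this scale understates the change of genes with low values. Mutants were compared with wild type, and with each other in the late window, in a model with the time point as a block and 42 residual degrees of freedom. The same model tested whether the change from the early to the late window differed between a mutant and wild type. Wild type over time was tested in a model of 9 strain and window means with 63 residual degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its fold change at least 2. Where a mutant is set against wild type, rose and fell mean higher and lower than wild type in the same window, not a change over time. All tests were 2-sided. Errors given with log2 differences are standard errors (SE) of the fit, and levels are means ± SD over the time points of a window in rescaled TPM.

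The comparisons, windows, thresholds, 42 gene lists with 799 members and the rule for naming genes were fixed before the data were examined. The 41 lists other than that of the deleted genes were tested with camera, the competitive list test of limma, at a preset correlation of 0.01 between genes and again with an estimated correlation. Adjusted p for lists are over the lists of a comparison. Camera sets a list against all other genes, so a list can be placed above them while its own median lies below 0. Of 451 tests of a list in a comparison, 176 passed with the preset correlation and 2 with an estimated one. An exact permutation test, which flips signs over time points for strain comparisons and permutes windows for the others, passed in 188. It tested the difference in a list's median level between groups. That difference need not equal the median of the gene differences given for a list, even in sign. The exact test sets a list against 0, so a shift common to all genes counts in it. The genes named for each mutant against wild type in the late window, and for wild type late against early, were the 10 highest and the 10 lowest log2 differences. They were taken among called nuclear protein-coding genes with a symbol, a mean of at least 10 rescaled TPM in the higher group and, between strains, the same sign at every time point. For the other comparisons 5 and 5 were taken by the same rule. Up to 4 members with the largest absolute difference were named per list described, and deleted and marker genes were kept apart. Some results that the rule selects are not reported here.

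Alternatives covered the deposited scale without rescaling, median-of-ratios scaling, pseudocounts of 0.1 and 5, a filter at 10 and none, no minimum fold change, fits without variance trend or robustness, without the block or with the compared strains alone. They also covered other windows, every other time point, means of neighbouring points, a spline of time with 5 degrees of freedom and each time point left out in turn. The steps were tested on simulated data in 3 sets of 5721 genes with 200 changed. Changes of 1.5 on the log2 scale were recovered for at least 90.3% of genes and changes of 3 for at least 99.3%. With independent time points the share of false calls was at most 1.68% in any comparison. With a correlation of 0.4 between neighbouring time points it was 4.70% to 9.76% for the strain comparisons and 22.1% to 25.7% for the changes over time. The residuals of the data had a median neighbour correlation of 0.163, between -0.135 and 0.383 over strains and windows. For the simulated late comparison of the cox4Δ strain, 2 of 2 shifted lists and 0 of the other lists passed. The simulated genes varied independently of each other. The simulation therefore cannot show how often lists whose genes vary together pass falsely at the preset correlation. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.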

Results

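The deleted genes were all but silent in the strains that lack them and expressed in the others. NDE1 (YMR145C, chromosome XIII 554793 to 556475), NDE2 (YDL085W, chromosome IV 303211 to 304848) and NDI1 (YML120C, chromosome XIII 28266 to 29807) encode NADH dehydrogenases that feed electrons to ubiquinone. In the strain with these deletions, called the NADH dehydrogenase mutant here, NDE1 lay between 0.170 and 3.22 TPM over 24 libraries, against 104 to 1391 TPM in 24 wild-type libraries and 128 to 277 TPM in 24 of the cox4Δ mutant. NDE2 did not exceed 0.602 TPM there, against 2.27 to 165 TPM in wild type, and NDI1 did not exceed 2.08 TPM, against 38.3 to 613 TPM. COX4 (YGL187C, chromosome VII 149704 to 150171), for a subunit of cytochrome c oxidase, lay between 0.396 and 5.21 TPM in the cox4Δ mutant, against 321 to 1554 TPM in wild type and 278 to 993 TPM in the NADH dehydrogenase mutant. Every library thus carried the genotype of its label. Each of the 4 genes has 1 coding segment, and positions are those of the build sacCer3.

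The gene HXT3, which encodes a low-affinity hexose carrier, was lost earlier in both mutants than in wild type. Wild type kept 1644 rescaled TPM at 14 h and 78.8 at 16 h. The NADH dehydrogenase mutant fell from 1688 at 11 h to 232 at 12 h, and the cox4Δ mutant from 1821 at 12 h to 501 at 13 h and 62.7 at 14 h. HXT7, for a high-affinity carrier, peaked next, at 8544 in the NADH dehydrogenase mutant (12 h), 6467 in the cox4Δ mutant (14 h) and 6857 in wild type (15 h). HXT7 and its neighbour HXT6 are near-identical, so reads may be shared between them. These values come from 1 library per strain and time, and the genes were chosen for their courses after the values were seen.

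The largest change between neighbouring time points involved more genes in the mutants than in wild type. Between 12 and 13 h, 1079 of 4428 genes changed at least 2-fold in the NADH dehydrogenase mutant (447 up and 632 down). Between 13 and 14 h, 1016 did so in the cox4Δ mutant (421 up and 595 down). The largest step in wild type was 377 genes (320 up and 57 down), between 14 and 15 h. It followed a step of 12 up and 190 down between 13 and 14 h. Steps of 364 genes between 9 and 10 h and 351 between 6 and 7 h were nearly as large. Each step rests on 1 library per time. At 14 h in the cox4Δ mutant SUC2, the invertase gene, reached 3060.3 rescaled TPM, against 559 an hour before. In the late window 13 of 18 mutant libraries were nearest, by Spearman correlation, to a wild-type library of 18 h or earlier. With Pearson correlation 18 of 18 were. The Spearman count includes the cox4Δ library of 18 h, which was nearest to wild type of the same hour. Margins over the same-time library varied. They were 0.9199 against 0.9195 for the NADH dehydrogenase mutant at 32 h and 0.888 against 0.866 for the cox4Δ mutant at 58 h. The highest correlation with any wild-type library was 0.974 to 0.988 for early cox4Δ libraries and 0.888 to 0.935 for late ones, and 0.976 to 0.987 and 0.896 to 0.934 for the NADH dehydrogenase mutant.

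**Figure D1:**
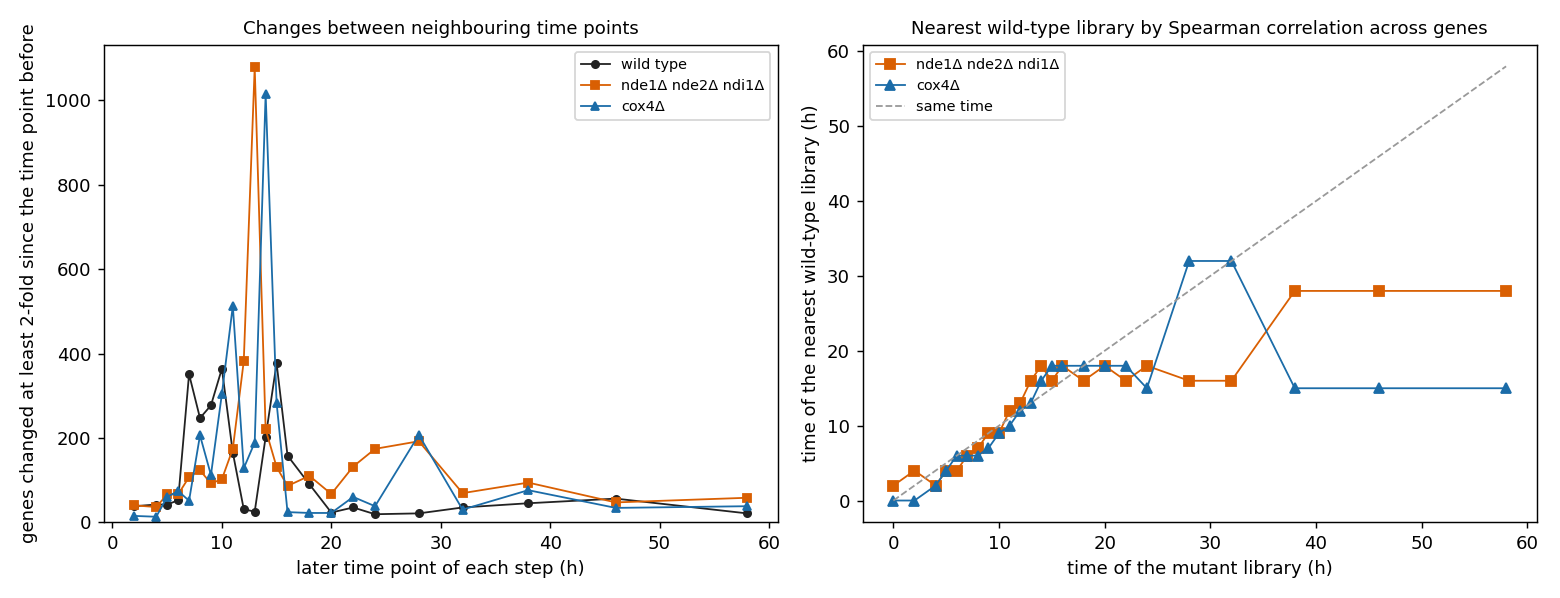
Number of genes that changed at least 2-fold between neighbouring time points for each strain against time in h, and the wild-type time in h of the library nearest to each mutant library by Spearman correlation. Each value comes from 1 library per strain and time.

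**Figure D2:**
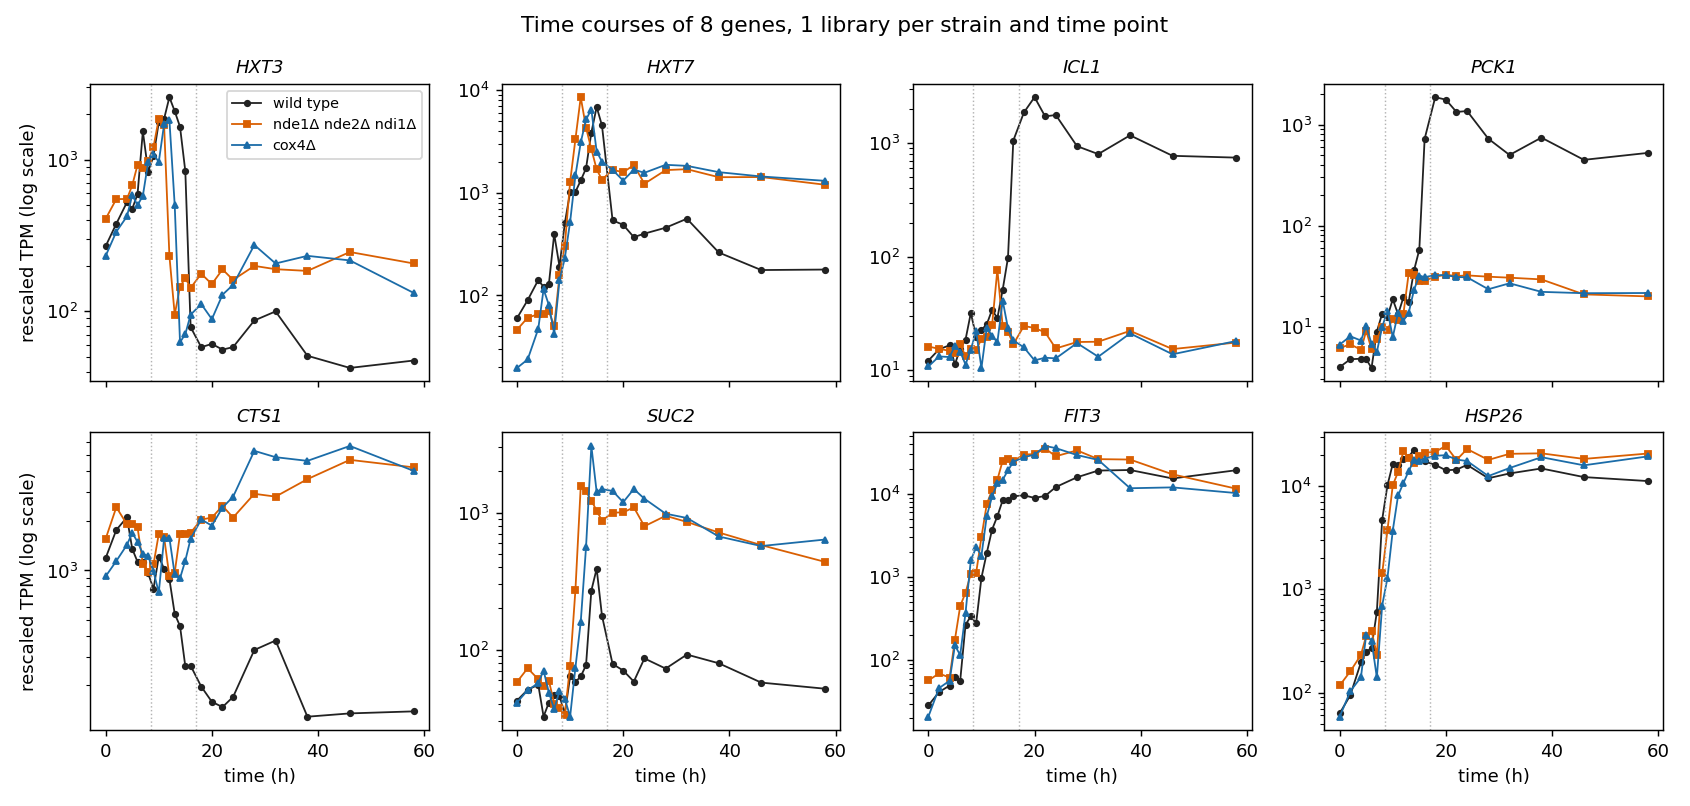
Rescaled TPM on a log scale against time in h for HXT3, HXT7, ICL1, PCK1, CTS1, SUC2, FIT3 and HSP26 in wild type, the NADH dehydrogenase mutant and the cox4Δ mutant. Each point is 1 library, and HXT3 in wild type fell from 1644 at 14 h to 78.8 at 16 h.

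In wild type HSP30, MLS1, JEN1, SIP18 and SFC1 rose most from the early window (n = 7) to the late window (n = 9). MLS1, which encodes malate synthase, rose by 7.63 on the log2 scale (SE 0.51, limma adjusted p = 7.1e-21), from 4.06 ± 2.00 to 1031 ± 433 rescaled TPM. SFC1, for the succinate/fumarate carrier, rose by 7.56 (SE 0.37, adjusted p = 1.8e-27) and PCK1, for PEP carboxykinase, by 7.05 (SE 0.40, adjusted p = 3.2e-24). JEN1, for a lactate and pyruvate carrier, rose by 7.59 (SE 0.63, adjusted p = 1.0e-16). HSP30, for a regulator of the plasma membrane proton pump, gained most of all with 7.81 (SE 0.77, adjusted p = 9.5e-14), followed by SIP18 with 7.59, FIT3 with 7.42, GRE1 with 6.94, HXT5 with 6.71 and ECM13 with 6.65. The strongest losses were UTR2, for a chitin cross-linking enzyme (-4.68, SE 0.45, adjusted p = 4.1e-14), HXT1 (-4.39, SE 0.45, adjusted p = 4.4e-13), the ammonium permease gene MEP2 (-3.81, SE 0.43, adjusted p = 1.4e-11), IMD2 (-3.77), the cyclin gene CLB1 (-3.68), SPS4 (-3.61), SFG1 (-3.57), GPP1 (-3.53) and CWP1 (-3.36). The genes deleted in the mutants also rose in wild type, NDE1 by 2.99, NDE2 by 4.04, NDI1 by 1.87 and COX4 by 1.33. In all, 1054 genes were higher and 841 lower in the late window, and the median gene moved by 0.05.

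Whole classes of genes moved together in wild type. All 12 genes of the glyoxylate cycle and gluconeogenesis rose from early to late, with a list median of 5.95, ICL1 at 6.16 and FBP1 at 6.03 (camera adjusted p = 2.2e-11, adjusted p = 0.256 with an estimated correlation). All 12 stationary phase genes rose, with a median of 4.24, SPG4 at 6.38 and SPS100 at 6.11 (camera adjusted p = 3.4e-08, adjusted p = 0.256 with an estimated correlation). All 63 cytosolic ribosomal protein genes fell, with a median of -1.79 and RPS22A at -3.06 (camera adjusted p = 1.6e-15, adjusted p = 0.340 with an estimated correlation). Of 14 ATP synthase genes 13 rose and 1 was not called, with ATP3 at 1.64 (camera adjusted p = 7.5e-07, adjusted p = 0.256 with an estimated correlation). Of 21 genes for respiratory complexes II to IV 20 rose, with SDH4 at 3.47 and SDH1 at 3.02 (camera adjusted p = 8.0e-07, adjusted p = 0.340 with an estimated correlation). Of 24 iron regulon genes 21 rose and 1 fell, with FIT2 at 5.59 and SIT1 at 4.88 (camera adjusted p = 6.8e-09, adjusted p = 0.256 with an estimated correlation). Of 34 Msn2/Msn4 stress genes 29 rose and 5 were not called (camera adjusted p = 7.1e-09, adjusted p = 0.340 with an estimated correlation). No cell number or viability was analysed here.

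In the middle window of wild type nearly all Msn2/Msn4 stress genes were already up and all cytosolic ribosomal protein genes down. SIP18, a hydrophilin gene, rose by 6.63 (SE 0.81, limma adjusted p = 3.8e-10) over the early window, with n = 8 against 7 time points. HSP30 rose by 6.23 (SE 0.79, adjusted p = 1.1e-09), GRE1 by 6.11 (SE 0.70, adjusted p = 6.4e-11), the small heat-shock gene HSP26 by 5.82 (SE 0.50, adjusted p = 4.2e-15) and NCA3 by 5.63. UTR2 fell by 4.30 (SE 0.46, adjusted p = 8.2e-12), IMD2 by 3.29, the histone H2A gene HTA2 by 3.20 (SE 0.45, adjusted p = 2.1e-08), CWP1 by 3.15 and DBP2 by 3.06 (SE 0.33, adjusted p = 8.2e-12). Of 34 Msn2/Msn4 genes 33 rose, with TKL2 at 5.47 and GND2 at 5.41 (camera adjusted p = 6.9e-24, adjusted p = 0.165 with an estimated correlation). All 63 cytosolic ribosomal protein genes fell, with a median of -1.62 (camera adjusted p = 3.1e-15, adjusted p = 0.310 with an estimated correlation). Of 10 histone genes 8 fell and 2 were not called, with HTB2 at -2.85 (camera adjusted p = 9.3e-07, adjusted p = 0.203 with an estimated correlation). A total of 702 genes were higher and 627 lower.

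In the late window of the NADH dehydrogenase mutant most genes of the glyoxylate cycle and gluconeogenesis were low, and genes such as CTS1 and DSE2 were high. SFC1 (YJR095W, chromosome X 609773 to 610741) was lowest relative to wild type, at 5.54 ± 2.55 against 481 ± 206 rescaled TPM (log2 difference -6.20, SE 0.26, limma adjusted p = 2.1e-25, n = 9 time points per strain). ICL1 (YER065C, chromosome V 285241 to 286914), for isocitrate lyase, followed with -5.94 (SE 0.34, adjusted p = 8.2e-20), then MLS1 with -5.67 (SE 0.29, adjusted p = 9.5e-22), PCK1 with -4.93 (SE 0.27, adjusted p = 6.7e-21), FBP1, for fructose-1,6-bisphosphatase, with -4.57 (SE 0.30, adjusted p = 4.5e-18) and MDH2, for cytosolic malate dehydrogenase, with -4.24 (SE 0.20, adjusted p = 2.2e-23). The chitinase gene CTS1 (YLR286C, chromosome XII 708448 to 710136), needed for cells to part after division, was the highest at 2995 ± 977 against 198 ± 90.4 rescaled TPM (3.96, SE 0.23, adjusted p = 3.8e-20).

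Other genes at the ends of the same ranking were ECM13 (-5.40, SE 0.29), the iron permease gene FTR1 (-4.41, SE 0.39), the spore wall gene SPS100 (-4.07, SE 0.20) and the amino acid permease gene AGP1 (-4.04, SE 0.19). Among the higher genes were the daughter-cell glucanase genes DSE2 (3.60, SE 0.23, adjusted p = 1.4e-18) and DSE4 (2.89, SE 0.16), DSE1 (2.99, SE 0.17), SUN4 (2.99, SE 0.19), SUC2 (3.47, SE 0.31, adjusted p = 9.7e-14), the phosphate cotransporter gene PHO89 (3.18, SE 0.39, adjusted p = 1.1e-09), the cell-wall mannoprotein genes TIP1 (3.12, SE 0.14) and HPF1 (3.03, SE 0.23), and SPG1 (2.82, SE 0.46, adjusted p = 5.0e-07). CTS1 had fallen in wild type by 2.85 (SE 0.27, limma adjusted p = 1.2e-14) from the early to the late window, a gene looked up after the mutant values were seen. All of the genes named from this ranking kept their sign at each of the 9 time points, because the naming rule required it. Of 5721 genes 155 were higher and 1681 lower in the late window, and the median gene lay at -0.65. With median-of-ratios scaling, which sets the median gene near 0, the split was 522 higher and 390 lower, and 155 and 390 were called under both scalings. The count of lower genes therefore depends on the scaling, whereas CTS1 (4.66), SFC1 (-5.55) and ICL1 (-5.25) changed under either.

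The glyoxylate and gluconeogenesis list had the lowest median in the NADH dehydrogenase mutant. Of 12 genes for the glyoxylate cycle and gluconeogenesis 9 fell, 1 rose and 2 were not called, with a median of -3.98 (-3.28 with median-of-ratios scaling). The 1 that rose was CAT8, for the transcription factor of this programme, at 1.17 (SE 0.22, adjusted p = 4.4e-06). Camera gave adjusted p = 0.00302 for the list, and adjusted p = 0.713 with an estimated correlation. Of 12 TCA cycle genes 10 fell, led by ACO1 (-3.45, SE 0.27), IDH1 (-2.84, SE 0.22) and IDH2 (-2.46), with a median of -1.29, whereas by median of ratios 5 fell and 1 rose, with a median of -0.59 (camera adjusted p = 0.0443, adjusted p = 0.713 with an estimated correlation). Of 24 iron regulon genes 14 fell and 10 were not called, with a median of -1.52, and by median of ratios 10 fell and 2 rose, with a median of -0.81 (camera adjusted p = 0.0184, adjusted p = 0.713 with an estimated correlation). Of 58 ribosome biogenesis genes 28 fell, with NOP7 at -2.13, ENP2 at -2.04 and a median of -0.99, but only 10 by median of ratios, with a median of -0.41 (camera adjusted p = 0.00789, adjusted p = 0.777 with an estimated correlation). Of 14 ATP synthase genes 4 fell, with TIM11 at -1.42 and ATP14 at -1.41, and 0 were called by median of ratios (camera adjusted p = 0.0443, adjusted p = 0.713 with an estimated correlation). The ATP synthase list also lost its camera call with that scaling (adjusted p = 0.350).

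Stress and storage lists stood above the rest of the genome in this mutant, though few members passed the 2-fold threshold. Of 34 Msn2/Msn4 genes 7 rose and 2 fell, with SPI1 at 2.61 (SE 0.30) and ALD3 at 1.63, and 15 rose and 0 fell by median of ratios (camera adjusted p = 1.1e-08, adjusted p = 0.713 with an estimated correlation). Of 21 Hsf1 chaperone genes 4 rose and 1 fell, with BTN2 at 2.37 (SE 0.26), FES1 at 1.73 and SSA4 at -1.02, and 10 rose and 0 fell by median of ratios (camera adjusted p = 3.6e-06, adjusted p = 0.484 with an estimated correlation). Of 18 trehalose and glycogen genes 4 rose and 1 fell, with GPH1 at 1.48, GSY1 at 1.47 and ATH1 at -1.28, and 9 rose and 0 fell by median of ratios (camera adjusted p = 6.4e-05, adjusted p = 0.713 with an estimated correlation). Of 6 high-affinity hexose transporter genes 3 rose and 1 fell, HXT7 by 2.10 (SE 0.30), HXT2 by 1.95 and HXT6 by 1.88 against HXT5 at -2.32 (camera adjusted p = 0.00554, adjusted p = 0.445 with an estimated correlation). The low-affinity genes HXT1 and HXT3 were both higher than in late wild type, by 1.53 and 1.62 (camera adjusted p = 0.00808, adjusted p = 0.444 with an estimated correlation). In wild type both had fallen from the early to the late window, with a median of -3.80. Phosphate starvation genes (2 of 18 rose and 2 fell) passed as higher with a median of -0.33 and a mean of 0.01, because camera compares a list with the other genes (adjusted p = 0.0193, adjusted p = 0.713 with an estimated correlation). With median-of-ratios scaling the high-affinity, low-affinity and phosphate lists lost their camera calls (adjusted p = 0.104, 0.0897 and 0.0529).

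Other lists had many lower members but did not stand apart from the rest of the genome. Of 25 cell cycle genes 15 fell and 2 rose, yet 1 fell and 3 rose by median of ratios (camera adjusted p = 0.894). Of 25 ergosterol genes 11 fell, and 4 by median of ratios, with ERG3 at -3.74 (SE 0.31, limma adjusted p = 1.4e-14), ERG25 at -2.97 (SE 0.26) and ERG5 at -2.78 (camera adjusted p = 0.370). Of 36 amino acid synthesis genes 8 fell, and the median changed from -0.53 to 0.15 with the scaling. The medians of the 63 cytosolic ribosomal protein genes (-0.55 to 0.16) and of 16 glycolytic genes (-0.52 to 0.19) changed sign in the same way. Of 8 selectable marker genes 0 were called, so no marker stood out in this strain.

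The cox4Δ mutant, which lacks a subunit of cytochrome c oxidase, had nearly the same late profile. ICL1 was the lowest at -6.28 (SE 0.34, limma adjusted p = 9.7e-21, n = 9), with 15.3 ± 3.06 rescaled TPM, and SFC1 came next at -6.17 (SE 0.26, adjusted p = 5.1e-25). MLS1 (-5.91, SE 0.29), ECM13 (-5.64, SE 0.29), PCK1 (-5.03, SE 0.27), FBP1 (-4.72, SE 0.30), MDH2 (-4.55, SE 0.20), AGP1 (-4.38, SE 0.19), ADH2 (-4.32, SE 0.21), for the ethanol-consuming alcohol dehydrogenase, and FTR1 (-4.22, SE 0.39) followed, with adjusted p of at most 4.5e-13. HXT13 (YEL069C, chromosome V 21537 to 23231), of the hexose transporter family, was the highest at 41.7 ± 8.11 against 1.03 ± 0.617 rescaled TPM (4.43, SE 0.53, adjusted p = 5.4e-10). CTS1 (4.23, SE 0.23, adjusted p = 3.4e-21), DSF1 (4.09, SE 0.45, adjusted p = 5.6e-11), for a mannitol dehydrogenase, DSE2 (3.99), SUC2 (3.75, SE 0.31, adjusted p = 1.0e-14), SUN4 (3.26), DSE1 (3.09), PHO89 (3.02, SE 0.39), HPF1 (2.98) and DSE4 (2.86) were the next. HXT13 and DSF1 have close copies, HXT17 and YNR073C, so reads may be shared among them.

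Of 5721 genes 141 were higher and 1504 lower in the late cox4Δ mutant, with the median gene at -0.61. By median of ratios 458 were higher and 388 lower, and 141 and 388 were called under both scalings. Among the deleted genes of the other strain, NDE1 was lower, at 186 ± 24.8 rescaled TPM against 1164 ± 160 in wild type (-2.63, SE 0.21, limma adjusted p = 2.6e-15). NDI1 was lower by 1.16 (SE 0.21, adjusted p = 3.4e-06) at 8 of 9 time points but only by 0.51 with median-of-ratios scaling. COX4 was not called in the NADH dehydrogenase mutant (-0.14).

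List results of the cox4Δ mutant followed those of the NADH dehydrogenase mutant. Of 12 glyoxylate and gluconeogenesis genes 11 fell, with a median of -4.10, and by median of ratios 8 fell and 1 rose, with a median of -3.45 (camera adjusted p = 0.000147, adjusted p = 0.748 with an estimated correlation). CAT8 was the exception at 0.90, not called with the first scaling. Of 12 TCA cycle genes 9 fell, with ACO1 at -3.49, IDH1 at -3.17 and CIT1 at -2.31, and 6 by median of ratios (camera adjusted p = 0.00708, adjusted p = 0.748 with an estimated correlation). Of 14 ATP synthase genes 7 fell, with ATP1 at -1.61, and 0 by median of ratios, where the camera call was lost at adjusted p = 0.0991 (camera adjusted p = 0.0103, adjusted p = 0.748 with an estimated correlation). Of 24 iron regulon genes 13 fell, with ARN1 at -3.38, VHT1 at -2.98 and SIT1 at -2.79, and by median of ratios 11 fell and 1 rose (camera adjusted p = 0.00932, adjusted p = 0.748 with an estimated correlation). Of 58 ribosome biogenesis genes 27 fell, with ENP2 at -1.97 and MAK16 at -1.87, and 9 by median of ratios (camera adjusted p = 0.0139, adjusted p = 0.799 with an estimated correlation). Of 34 Msn2/Msn4 genes 7 rose and 4 fell, with SPI1 at 1.89 and OM45 at -1.39, whereas 12 rose and 0 fell by median of ratios (camera adjusted p = 2.6e-06, adjusted p = 0.748 with an estimated correlation). Of 21 Hsf1 genes 4 rose and 2 fell, with BTN2 at 2.56 and FES1 at 1.86, whereas 8 rose and 0 fell by median of ratios (camera adjusted p = 9.5e-06, adjusted p = 0.603 with an estimated correlation).

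Most mitochondrially encoded transcripts tested were higher in the late cox4Δ mutant than in wild type, although their values were very low throughout. In the cox4Δ mutant 5 of 6 tested genes rose and COX1 was not called, with COB at 1.33 (SE 0.26, limma adjusted p = 1.6e-05, 7 of 9 time points), ATP6 at 1.31 and OLI1 at 1.23. COB stood at 6.67 ± 10.5 against 1.27 ± 1.11 TPM on the rescaled scale, with 34.6 in the library of 58 h alone. Camera gave adjusted p = 1.7e-05 for the list and adjusted p = 0.359 with an estimated correlation. In the NADH dehydrogenase mutant 0 of 6 were called, and 3 rose by median of ratios, with a list median of 0.70 (camera adjusted p = 0.00147, adjusted p = 0.484 with an estimated correlation). That call was lost with median-of-ratios scaling (adjusted p = 0.0914). Further lists of the cox4Δ mutant had many lower members. Of 23 sulfur assimilation genes 13 fell, with MET10 at -2.47 and MMP1 at -2.44, whereas by median of ratios 5 fell and 1 rose (camera adjusted p = 0.131, and 0.0420 by median of ratios), and of 8 retrograde response genes 5 fell (camera adjusted p = 0.259). The Yap1 list of the cox4Δ mutant (3 of 21 rose and 3 fell) passed as higher with a median of -0.34, and 0.31 by median of ratios (camera adjusted p = 0.0248, adjusted p = 0.748 with an estimated correlation).

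**Figure D3:**
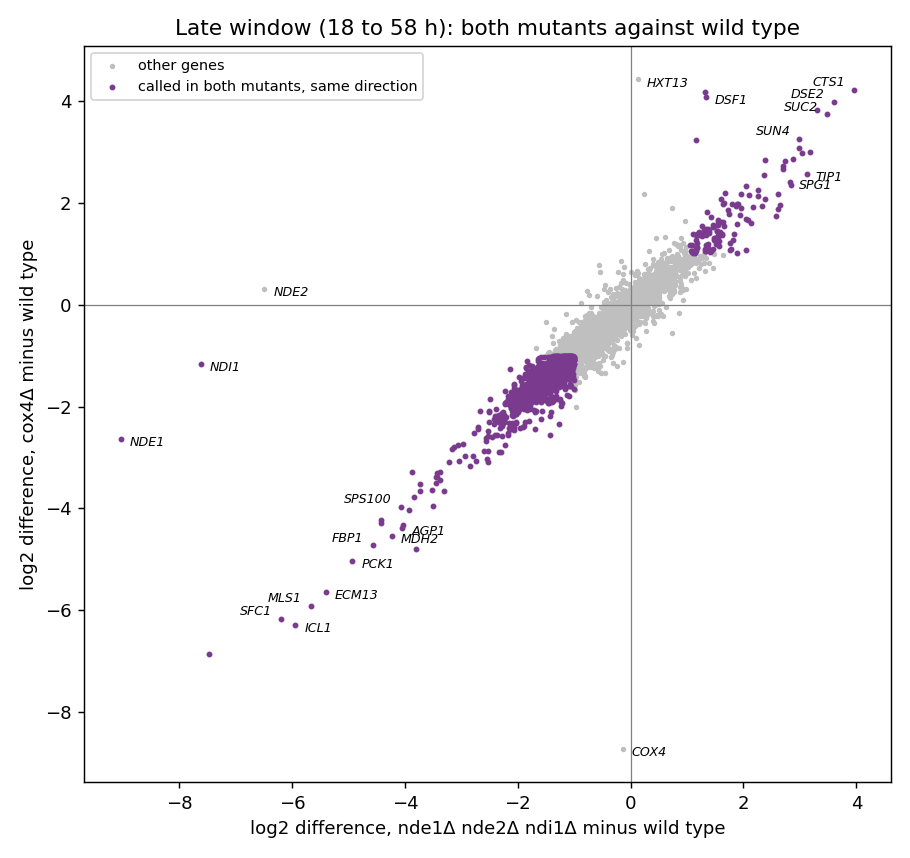
Log2 difference from wild type of the NADH dehydrogenase mutant (horizontal) and of the cox4Δ mutant (vertical) for 5721 genes in the late window, n = 9 time points per strain. Genes called in both mutants in the same direction are coloured, 118 higher and 1346 lower.

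**Figure D4:**
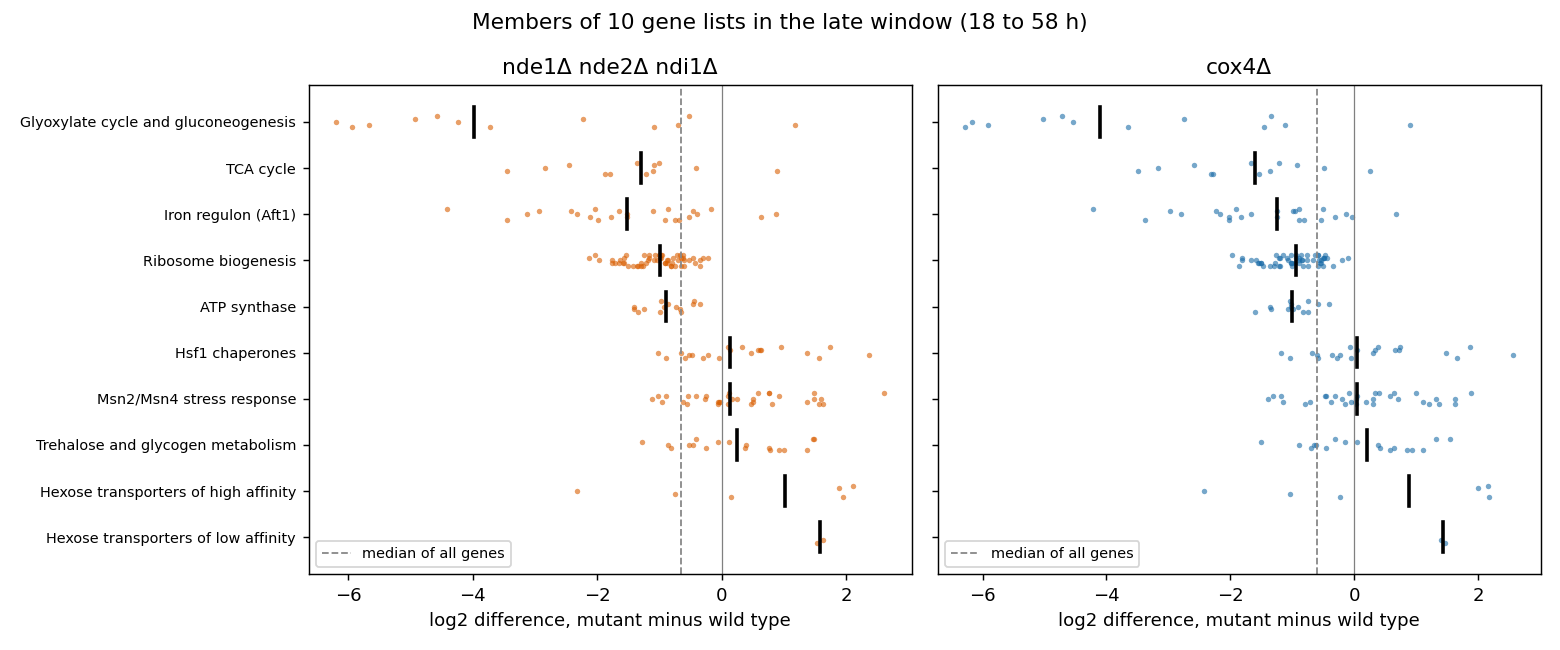
Log2 difference from wild type in the late window for the genes of 10 lists in each mutant, with the median of all genes as a dashed line (-0.65 in the NADH dehydrogenase mutant and -0.61 in the cox4Δ mutant).

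Most late changes were common to both mutants, which lack different parts of the respiratory chain. The genes called higher in both numbered 118, against 3.82 for independent sets, and those lower in both 1346, against 442, while 0 were called in opposite directions. The log2 differences correlated at r = 0.93 over all genes. A shared wild type alone produces a correlation, which reached 0.50 in simulation. When odd and even wild-type time points served the mutants separately, 110 higher and 1250 lower genes, or 117 and 1259 with the points exchanged, were still shared (r = 0.887 and 0.910). Both sets of points come from the same wild-type time course. A trait of that culture or of its plate rows would enter both, so this split cannot remove it. By median of ratios 401 were higher and 294 lower in both, against 41.8 and 26.5 for independent sets.

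A small set of genes told the mutants apart. HXT13 was higher in the cox4Δ mutant by 4.31 (SE 0.53, limma adjusted p = 1.3e-07, n = 9 time points per strain), with 41.7 ± 8.11 against 1.24 ± 0.737 rescaled TPM. DSF1 (YEL070W, chromosome V 19589 to 21097), which lies beside it, was higher by 2.75 (SE 0.45, adjusted p = 8.5e-05). The lactate dehydrogenase genes DLD1 (1.35, SE 0.13, adjusted p = 2.1e-10) and CYB2 (1.18, SE 0.22, adjusted p = 0.00097), whose products pass electrons to cytochrome c, and ECM3 (1.18, SE 0.16, adjusted p = 1.0e-06) were also higher. With means of neighbouring time points HXT13 (adjusted p = 0.0608), DSF1 (0.288), ECM3 (0.0608) and CYB2 (0.391) lost their calls, and HXT13, DSF1 and CYB2 also with every other time point, so only DLD1 of these was called under every alternative. No gene met the naming rule among the lower ones. In all 12 genes were higher and 5 lower, the 4 deleted genes included, and 12 and 7 by median of ratios. At unadjusted p 699 genes passed 0.05. Of the lists, 7 passed camera with 0 members called, among them the TCA cycle with a median of -0.28 (adjusted p = 0.00401, adjusted p = 0.854 with an estimated correlation). None of the 7 kept that call with an estimated correlation, and by exact test 0 lists passed. The smallest p of the exact test at 9 time points, 0.00391, passes adjustment only where several lists reach it.

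In the early window a few phosphate and iron genes were called higher in the NADH dehydrogenase mutant. FIT2, for a cell-wall protein that retains siderophore iron, was higher by 1.64 (SE 0.18, limma adjusted p = 1.8e-08, n = 7 time points per strain). The acid phosphatase gene PHO12 was higher by 1.63 (SE 0.22, adjusted p = 1.2e-06), the phosphate transporter gene PHO84 by 1.41 (SE 0.29, adjusted p = 0.0038), FIT3 by 1.35 (SE 0.28, adjusted p = 0.0038) and SPL2 by 1.27 (SE 0.26, adjusted p = 0.0038). FIT2, PHO84 and FIT3 lost their calls without the time block, and FIT3 also without 6 h (adjusted p = 0.0867). With every other time point from the second on FIT2 alone kept its call. The FIT genes, and PHO12 with its copy PHO11, are similar enough for reads to be shared. Only 11 genes were higher and 3 lower, the 3 being the deleted genes, and 327 genes passed 0.05 at unadjusted p. Of 18 phosphate starvation genes 3 rose, or 4 when adjusted over the list alone, with a median of 0.62 (camera adjusted p = 2.5e-15, adjusted p = 0.0278 with an estimated correlation). Of 14 ATP synthase genes 0 were called, but the list median was -0.42 (camera adjusted p = 2.0e-21, adjusted p = 0.0173 with an estimated correlation). These were the only lists to keep a call with an estimated correlation. Of 24 iron genes 3 rose, with a median of 0.46 (camera adjusted p = 1.7e-15, adjusted p = 0.0833 with an estimated correlation). Of 14 drug efflux genes 2 rose, among them PDR5 by 1.13 (camera adjusted p = 5.0e-05, adjusted p = 0.0833 with an estimated correlation).

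The early cox4Δ mutant had PHO12 and SPL2 high as well, and ENA2, TPO2 and HXT4 low. NDJ1, for a meiotic telomere protein, was higher by 1.79 (SE 0.25, limma adjusted p = 1.8e-06, n = 7), PHO12 by 1.62 (SE 0.22, adjusted p = 1.0e-06), ARG3 by 1.55 (SE 0.35, adjusted p = 0.0059), the amino acid permease gene DIP5 by 1.54 (SE 0.20, adjusted p = 7.4e-07) and SPL2 by 1.54 (SE 0.26, adjusted p = 9.4e-05). ENA2, for a sodium pump, was lower by 2.38 (SE 0.36, adjusted p = 1.2e-05), TPO2 by 1.90 (SE 0.33, adjusted p = 0.00011), HXT4 by 1.69 (SE 0.46, adjusted p = 0.026), HXT7 by 1.34 (SE 0.34, adjusted p = 0.016) and RTC3 by 1.27 (SE 0.26, adjusted p = 0.0022). HXT4 lost its call without the library times of 4, 7 or 8 h (adjusted p = 0.294 without 7 h), and HXT7 without 2, 4 or 7 h. ARG3 lost its call without 7 h (adjusted p = 0.0525) and with the compared strains alone (0.0566). ARG3, TPO2, HXT4, HXT7 and RTC3 lost theirs without the time block, and with every other time point from the second on DIP5 alone of the 10 genes kept its call. In all 27 genes were higher and 17 lower, or 30 and 14 by median of ratios. Of 18 phosphate genes 3 rose, or 5 over the list alone (camera adjusted p = 8.1e-08, adjusted p = 0.272 with an estimated correlation). Of 8 retrograde response genes 2 rose, CIT2 by 1.03 and ATO3 by 1.07 (camera adjusted p = 9.2e-07, adjusted p = 0.272 with an estimated correlation). In the Msn2/Msn4 list 2 of 34 genes fell, with a median of -0.61 (camera adjusted p = 3.0e-15, adjusted p = 0.402 with an estimated correlation). By exact test this list did not pass (adjusted p = 0.466), and its difference in median level had an SD of 0.90 over the 7 time points. The early NADH dehydrogenase mutant had 0 members of these 2 lists called, with medians of 0.56 for retrograde and -0.27 for Msn2/Msn4 genes. Camera gave adjusted p = 1.2e-05 and 1.6e-15 there, and 0.225 and 0.230 with an estimated correlation. The ATP synthase list of the cox4Δ mutant had 0 of 14 genes called and a median of -0.53 (camera adjusted p = 2.8e-13, adjusted p = 0.197 with an estimated correlation). Beyond these phosphate lists, counts adjusted over a list alone differed from those over all genes only by 1 gene, for a mating-type list here and for the cytosolic ribosomal proteins in a change over time. Wild type changed 351 genes at least 2-fold between 6 and 7 h. The cox4Δ libraries of 7 and 8 h were nearest to wild type of 6 h, with same-time correlations of 0.941 and 0.938 against 0.983 at 6 h. The early window may therefore also mix growth phases, and growth was not analysed here.

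In the middle window the NADH dehydrogenase mutant departed from wild type most in ZPS1, FIT3, AGP1 and the biotin genes BIO3 and BIO4. ZPS1, a zinc-regulated gene, was higher by 1.87 (SE 0.21, limma adjusted p = 5.4e-09, n = 8 time points per strain), FIT3 by 1.66 (SE 0.26, adjusted p = 5.9e-06), TIP1 by 1.36 (SE 0.15, adjusted p = 2.5e-09), the mitochondrial pyruvate carrier gene MPC2 by 1.36 (SE 0.12, adjusted p = 6.8e-12) and CIT3 by 1.25 (SE 0.22, adjusted p = 3.2e-05). AGP1 was lower by 2.84 (SE 0.20, adjusted p = 1.1e-15), the biotin synthesis genes BIO3 by 2.81 (SE 0.36, adjusted p = 1.6e-07) and BIO4 by 2.77 (SE 0.33, adjusted p = 2.0e-08), SPS100 by 2.39 (SE 0.21, adjusted p = 3.4e-12) and the sulfiredoxin gene SRX1 by 2.13 (SE 0.34, adjusted p = 8.5e-06). The split was 45 higher and 210 lower with the median gene at -0.34, but 105 higher and 45 lower by median of ratios, with 45 and 45 called under both. FIT3 lost its call without the time block (adjusted p = 0.0553), and CIT3 lay under the 2-fold threshold without 13 h (0.93). The count of 255 moved to 124 without 14 h and to 492 without 10 h, and an exchange of strain labels within time points reached 278. Of 63 cytosolic ribosomal protein genes 6 fell, and 0 by median of ratios (camera adjusted p = 0.000649, adjusted p = 0.963 with an estimated correlation). Of 25 ergosterol genes 6 fell, with ERG3 at -1.99 and ERG5 at -1.85, and 4 by median of ratios (camera adjusted p = 0.0101, adjusted p = 0.963 with an estimated correlation). Strains shut down HXT3 at different hours of this window, so it may mix growth phases, and growth was not analysed here.

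The cox4Δ mutant shared most of these middle-window genes. ZPS1 was higher by 1.84 (SE 0.21, limma adjusted p = 6.5e-09, n = 8), MPC2 by 1.52 (SE 0.12, adjusted p = 1.6e-13), the pyruvate carboxylase gene PYC1 by 1.46 (SE 0.25, adjusted p = 3.6e-05), FIT3 by 1.43 (SE 0.26, adjusted p = 7.2e-05) and DLD1 by 1.42 (SE 0.14, adjusted p = 1.9e-10), with the call of FIT3 lost without the time block (adjusted p = 0.145). ENA2 was lower by 3.31 (SE 0.34, adjusted p = 2.6e-10), BIO4 by 3.02 (SE 0.33, adjusted p = 1.5e-09), BIO3 (SE 0.36, adjusted p = 2.9e-08) by nearly as much, AGP1 by 2.77 (SE 0.20, adjusted p = 5.9e-15) and SPS100 by 2.69 (SE 0.21, adjusted p = 7.6e-14). Here 29 genes were higher and 133 lower with the median gene at -0.27, and 51 higher and 64 lower by median of ratios, with 29 and 64 under both. Of 12 TCA cycle genes 3 fell, IDH1 by 1.23, KGD2 by 1.02 and IDH2 by 1.01, and 0 by median of ratios (camera adjusted p = 0.00355, adjusted p = 0.938 with an estimated correlation). In the Msn2/Msn4 list 4 of 34 genes fell under either scaling, SSA4 by 1.70, TKL2 by 1.40, SSA3 by 1.35 and GND2 by 1.27 (camera adjusted p = 0.0464, adjusted p = 0.938 with an estimated correlation).

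The change from the early to the late window differed between mutants and wild type for the same genes. In the NADH dehydrogenase mutant the rise of SFC1 fell short of wild type by 6.17 on the log2 scale (SE 0.39, limma adjusted p = 6.1e-17, 7 early and 9 late time points per strain), that of MLS1 by 5.87 (SE 0.45), ICL1 by 5.83 (SE 0.52), ECM13 by 5.74 (SE 0.43) and PCK1 by 5.20 (SE 0.41). CTS1 (3.69, SE 0.34, adjusted p = 4.8e-12), HPF1 (3.60, SE 0.35), DSE2 (3.24, SE 0.34), SUC2 (3.21, SE 0.46) and HXT7 (3.10, SE 0.46, adjusted p = 1.7e-07) had a more positive change than in wild type. Such a value can come from a fall in wild type, as CTS1 had, and does not by itself mean a rise in the mutant. Gained more or less is used below in this sense. For the cox4Δ mutant the lowest were SFC1 (-6.16, SE 0.39, adjusted p = 6.6e-17), MLS1 (-6.08), ICL1 (-6.01), ECM13 (-5.62) and PCK1 (-5.38), and the highest HXT13 (4.54, SE 0.81, adjusted p = 7.5e-06), DSF1 (4.32), CTS1 (4.27), HPF1 (4.21) and DSE2 (3.93). The counts were 160 higher and 1917 lower for the NADH dehydrogenase mutant, or 568 and 440 by median of ratios, with 160 and 440 under both. For the cox4Δ mutant they were 201 and 1492, or 549 and 444, with 200 and 444 under both. The median gene lay at -0.72 and -0.56.

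List differences in these changes over time were as large. Of 12 glyoxylate and gluconeogenesis genes 10 gained less and 1 more in the NADH dehydrogenase mutant, with a median of -3.85 (8 and 1 by median of ratios, camera adjusted p = 0.000416, adjusted p = 0.571 with an estimated correlation), and 11 and 1 in the cox4Δ mutant, with a median of -3.94 (9 and 1 by median of ratios, camera adjusted p = 2.9e-06, adjusted p = 0.368 with an estimated correlation). Of 24 iron genes 18 gained less in the NADH dehydrogenase mutant, with FTR1 at -4.98 and SIT1 at -4.20 (12 by median of ratios, camera adjusted p = 1.8e-05, adjusted p = 0.571 with an estimated correlation), and 15 in the cox4Δ mutant, with FTR1 at -4.42 (12 by median of ratios, camera adjusted p = 0.000255, adjusted p = 0.731 with an estimated correlation). In the Msn2/Msn4 list 10 of 34 genes gained more in the NADH dehydrogenase mutant, with SPI1 at 2.76 and ALD3 at 2.45 (22 by median of ratios, camera adjusted p = 9.8e-15, adjusted p = 0.509 with an estimated correlation), and 13 in the cox4Δ mutant, with ALD3 at 2.68 and SPI1 at 2.47 (24 by median of ratios, camera adjusted p = 7.8e-14, adjusted p = 0.368 with an estimated correlation). The medians of this list against wild type were -0.27 and -0.61 early and 0.14 and 0.04 late, so these differences lay partly in the early window. The exact test of list medians passed for 33 and 31 lists in the late comparisons of the NADH dehydrogenase and cox4Δ mutants, and 31 and 27 in their changes over time. That test sets a list against 0 and not against the other genes, so a shift common to all genes adds to these counts. In the early and middle windows 0 lists passed, but the smallest possible p there was 0.0156 with 7 time points and 0.00781 with 8. Lists at that p had adjusted p = 0.0915 in the early NADH dehydrogenase mutant and 0.0712 in the middle cox4Δ mutant. The 0 counts are therefore no evidence of fewer shifted lists. For phosphate starvation genes in the late NADH dehydrogenase mutant the tested difference was 0.86, against a median gene difference of -0.33.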

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

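The tests for the late fall, the glyoxylate genes and the mitochondrial transcripts, and those that exchange strains, were all chosen only after the results were seen. Those for the late fall, for a delay of the glyoxylate genes and for carried-over DNA had their measure or bound restated after earlier versions had been run. Library measures were examined in 27 tests, several for each strain and window, of which chance marks about 1 in 20, and 4 libraries stood apart.

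Most genes called in the late window were lower in both mutants, and the share of each library held by its 10 highest genes rose at the same time, to 27.7 ± 2.59% in the NADH dehydrogenase mutant and 29.2 ± 4.31% in the cox4Δ mutant against 17.3 ± 1.41% in wild type (n = 9 libraries each). TPM are shares of a fixed total, so a few genes taking most of the values lower all the rest. With the total taken over the genes other than the 10 highest of each strain, the lower share of calls went from 91.6% to 82.9% in the NADH dehydrogenase mutant and from 91.4% to 79.8% in the cox4Δ mutant, and the median gene from -0.65 to -0.44 and from -0.61 to -0.36. Without the 50 highest of each strain the share was 75.7% and 72.1% and the median gene lay at -0.33 and -0.25, so high genes account for part of the shift and the source of the rest is open. A change in RNA per cell was not tested, and no spike-in is given in the sources used here.

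Genes of the glyoxylate cycle and gluconeogenesis were low in both mutants in the late window. A few genes taking most of the values can be excluded as the sole cause, since the list median was still -3.28 in the NADH dehydrogenase mutant and -3.45 in the cox4Δ mutant with a scaling by the median gene. The highest late library of a gene reached a median of only 8.39% and 7.05% of its late wild-type mean, and over all times 19.8% and 13.8%. In the lowest late wild-type library this median was 55.3%. These values argue against a delay of the mutants within the 58 h sampled for the list as a set. A count of genes that reach 50%, run first, fell between its bounds, and the median was chosen after it. ICL1, MLS1, MDH2, PCK1, FBP1, SFC1, JEN1 and IDP2 stayed below 50% in the late libraries of both mutants. Of 12 genes 4 in the NADH dehydrogenase mutant and 2 in the cox4Δ mutant reached 50%, among them CAT8, which was not lower, and a delay is open for the others of these and beyond 58 h.

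Mitochondrially encoded transcripts summed to 54.5 TPM in the NADH dehydrogenase mutant and 186 TPM in the cox4Δ mutant at 58 h, against late medians of 17.5 and 18.5. The intron-encoded frames reached only 9.98% and 6.96% of the mean of the 8 genes. This argues against mitochondrial DNA carried over into the libraries as the main source. The same holds for genomic DNA, which raises these transcripts only through its mitochondrial part. The frames themselves summed to 6.12 and 14.6 TPM at 58 h, their highest late value in each mutant, so a part from DNA is open. The transcript annotation is not given, so how reads were shared between these frames and the 8 genes is unknown. Nuclear genes of low values, at 0.744 and 1.19 times their level in the other late libraries, add nothing here because they lie near the floor of 0.1 TPM. Transcripts of mitochondria are scarce in all libraries, and no biological explanation was tested.

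The NADH dehydrogenase mutant at 16 h also stood apart, with 15.4 TPM of mitochondrial transcripts, and the wild type at 5 h had 17.9% of its values in the 10 highest genes. Neither library was left out.

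Exchanging strains within time points asked whether an arbitrary assignment of libraries to strains gives as many calls. It takes the time points as exchangeable, and with 1 culture per strain it leaves chance differences between cultures open. For the early window the real assignment was the only 1 of 64 to reach its count, 14 for the NADH dehydrogenase mutant (highest other 6, with the 3 deleted genes among the 14) and 44 for the cox4Δ mutant (highest other 21). In every strain comparison the deleted genes, and any constant difference between single cultures, set the real assignment apart by design. These counts therefore cannot tell an effect of the deletions from one of the cultures. In the middle window of the NADH dehydrogenase mutant 2 of 100 reached the real count of 255, and the highest other, 278, exceeded it, so the number itself has little weight. For the cox4Δ mutant 1 of 100 did, the real one (162 against 117). Late counts were likewise reached by 1 of 100 only, 1836 against 1090 for the NADH dehydrogenase mutant and 1645 against 1043 for the cox4Δ mutant. The same held for wild type over time with windows exchanged, 1329 against 800 in the middle and 1895 against 1346 in the late window.

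The direct comparison of the mutants gave 17 genes, with the 4 deleted genes among them. The highest other count was 11, and of 100 assignments only the real 1 reached its count. The deleted genes set the real assignment apart by design, so the margin for the other genes is smaller. HXT13 differed by 4.31, DSF1 by 2.75, DLD1 by 1.35, ECM3 by 1.18 and CYB2 by 1.18. The change over time differed for 2077 genes in the NADH dehydrogenase mutant (highest other 1365, 1 of 100 as large) and for 1693 in the cox4Δ mutant (highest other 1637, 1 of 100 as large). The latter margin is narrow.

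Genes with the largest such differences in the NADH dehydrogenase mutant were CTS1 (3.69), HPF1 (3.60), DSE2 (3.24), SUC2 (3.21), HXT7 (3.10), SFC1 (-6.17), MLS1 (-5.87), ICL1 (-5.83), ECM13 (-5.74) and PCK1 (-5.20). In the cox4Δ mutant they were HXT13 (4.54), DSF1 (4.32), CTS1 (4.27), HPF1 (4.21), DSE2 (3.93), SFC1 (-6.16), MLS1 (-6.08), ICL1 (-6.01), ECM13 (-5.62) and PCK1 (-5.38).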

How the results depend on the processing

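The alternative that asks for a call under both scalings was added after the data were seen, and the others were fixed before. Counts here add higher and lower genes. They are given for the NADH dehydrogenase mutant and the cox4Δ mutant against wild type unless another comparison is named.

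Median-of-ratios scaling lowered the late counts to 912 and 846, the middle count of the NADH dehydrogenase mutant to 150, the changes over time to 1008 and 993 and the shared late genes to 695. By construction it removes the common shift of genes. Under both scalings in the same direction 90 and 93 genes were called in the middle window, 545 and 529 in the late window and 600 and 644 in the changes over time.

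A pseudocount of 5 gave 1044 and 938 in the late window, 1229 and 1015 in the changes over time, 137 in the middle window of the NADH dehydrogenase mutant and 26 in the early window of the cox4Δ mutant. It shrinks differences of genes with low values by construction. A pseudocount of 0.1 gave 416 in the middle window of the NADH dehydrogenase mutant.

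With no minimum fold change the counts were 39, 3006 and 4454 in the early, middle and late windows of the NADH dehydrogenase mutant, 180, 1714 and 4359 for the cox4Δ mutant, 97 between the mutants, 3883 and 3447 in the changes over time, and 3048 and 3715 for wild type in the middle and late windows.

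Without the replicate block 7 and 19 genes were called in the early window, and it gave no value for the comparisons within wild type.

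Every other time point, first set, gave 8 and 16 in the early window, 431 and 356 in the middle window and 7 between the mutants. The second set gave 4 and 8 in the early window and 103 in the middle window of the cox4Δ mutant. Means of neighbouring time points, 3 per window, gave 6 and 18 early, 95 in the middle window of the NADH dehydrogenase mutant and 5 between the mutants. Windows of 4 to 8, 10 to 15 and 24 to 58 h gave 404 in that middle window. For these settings the cause was not tested.

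With each time point left out in turn, the counts of the NADH dehydrogenase mutant ranged over 13 to 17 early, 124 (without 14 h) to 492 (without 10 h) in the middle window and 1765 to 1962 late. Those of the cox4Δ mutant ranged over 28 (without 7 h) to 48 (without 0 h), 128 to 209 and 1556 to 1769. Counts between the mutants ranged over 16 to 19, those of the changes over time over 1982 to 2200 and 1630 to 1819, and those of wild type over 1227 to 1467 and 1841 to 1991. The middle window of the NADH dehydrogenase mutant thus rests on single hours, and the cause was not tested.

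An estimated inter-gene correlation left 2 lists. The deposited scale, other filters, plain variance moderation, a spline of time and fits with the compared strains alone moved no count by more than 1.5 times. Of 1916 alternative results for the 130 named gene results 52 were weaker and 0 reversed, and of 3120 with a time point left out 9 were weaker and 0 reversed.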

Other observations

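The regulator gene CAT8 was not lower where its targets were. It rose by 1.17 (SE 0.22, limma adjusted p = 4.4e-06) in the late NADH dehydrogenase mutant, with ICL1 at -5.94 and PCK1 at -4.93. Transcript level of the regulator therefore did not follow that of the targets, and the activity of the protein was not analysed here.

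HXT13 and DSF1 lie side by side on chromosome V, and HXT17, YNR073C and YNR071C lie together on chromosome XIV (770440 to 776300). All 5 were higher in the late cox4Δ mutant than in the NADH dehydrogenase mutant, HXT17 by 1.95 (SE 0.28, limma adjusted p = 4.1e-06), YNR073C by 2.87 (SE 0.40, adjusted p = 2.1e-06) and YNR071C by 2.09 (SE 0.36, adjusted p = 0.00016), besides HXT13 (4.31) and DSF1 (2.75). HXT13 resembles HXT17 and DSF1 resembles YNR073C, so reads of one site cannot be told from those of the other with certainty. HXT13 reached 526 rescaled TPM at 14 h in the cox4Δ mutant, the hour after HXT3 was lost.

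The small gene YDL085C-A (chromosome IV 302464 to 302670) lies beside NDE2. It was lower by 1.28 (SE 0.25, limma adjusted p = 0.0011) in the late cox4Δ mutant than in the NADH dehydrogenase mutant, in which NDE2 is deleted, and a neighbour effect of the deletion was not tested.

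CUP1-1 held 8.45 ± 3.34% of the late cox4Δ libraries and 5.87 ± 1.89% of those of the NADH dehydrogenase mutant, against 1.11 ± 0.286% in wild type (n = 9 each). Its log2 differences were 2.85 (SE 0.29, limma adjusted p = 8.1e-12) and 2.38 (SE 0.29, adjusted p = 8.8e-10). It is a tandem array, and the copy number of these strains is not given in the sources used here. RRT15, which lies in the ribosomal DNA, held 2.36 ± 1.18% and 1.98 ± 0.897%, and residual ribosomal RNA was not analysed here.

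OLE1 and ERG3 were low in both late mutants, although the ergosterol list did not stand apart from other genes. OLE1, for the fatty acid desaturase, fell by 2.28 (SE 0.19, limma adjusted p = 1.4e-14) and 2.36, and still by 1.57 and 1.70 with median-of-ratios scaling. ERG3 fell by 3.74 and 3.52. PMA1, for the plasma membrane proton pump, fell by 1.88 (SE 0.22, adjusted p = 2.1e-10) and 1.95. MPC2, for a pyruvate carrier of mitochondria, was higher by 1.90 (SE 0.12, adjusted p = 4.3e-19) in the cox4Δ mutant.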
